A study of Homo sapiens with 9 samples.

How the data were processed

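RNA from HepG2 cells was measured in 9 cultures, 3 exposed to 125 µM TBOEP, 3 to 2.5 µM TBOEP and 3 to 0.1% DMSO alone, all for 72 h, per the labels. Each replicate was seeded, treated, extracted and sequenced separately, per the labels' protocols. RNA was isolated with TRIzol and RNeasy columns, libraries were made with the TruSeq Stranded mRNA kit, which keeps strand and selects polyadenylated RNA, and paired reads of 50 bp were sequenced on a HiSeq 1500, per the labels' protocols. Reads were aligned to the UCSC hg19 genome and assigned to annotated genes with CLC Genomics Workbench, per the series' design text; its version and whether the counting used strand are not given in the sources used here.

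Each deposited file holds 1 library with 57773 features, and the files pair every feature with a gene name and a position. The deposited read counts per gene (total, unique, exon and intron reads) are whole numbers and not normalised, per the file headers. The deposited RPKM values are exon reads scaled by exon length and by library depth, per the file headers. The deposited normalised signal was made by the authors by quantile normalisation across libraries, per the series' design text, and has the same total and maximum in all 9 libraries. The authors tested differences with Baggerly's statistic and a false discovery rate of 5%, per the series' design text.

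Total gene reads were used as deposited, exon and intron reads together; every named feature was kept, and the values labelled expression in the files equalled the exon reads. Positions are those of the files with 1 added to the start, since 68.9% of the 33420 features that matched GENCODE v44 on GRCh37 by name then had the same start and 1.20% did without. Besides the genes said to overlap another where their values are given, ACADVL, AJUBA, APOA2, ARG1, ATP5H, CCNA2, CD68, F11, FCER1G, GAPDH, GPX2, HSPA1A, ITGA2, KIF20A, LCAT, LGR5, LYZ, NR2F1, PCK2, PDK1, RPL31, RPL36, RPL6, RPS18, SLC38A2, SLC51A, SPC24, TCF7, TP53INP1, TPI1 and WARS overlap another tested gene and are uncertain to the extent that they share its reads.

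Genes were filtered with filterByExpr, which kept 12901, and scaled by TMM. The quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 was fitted to all 9 libraries in 3 groups with no covariate, and each comparison is a two-sided contrast with Benjamini-Hochberg adjustment over the 12901 genes and a threshold of 0.05. The common biological coefficient of variation was 10.1%. CPM values are scaled by TMM, and SE values come from the same fit. Gene lists, 43 in all with 1420 entries of which 1410 were in the files, were fixed before the data were examined; 40 had at least 5 tested members and were tested with camera of limma 3.58.1, with a preset correlation of 0.01 and with an estimated one, and with fry. A gene can be in several lists.

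The genes named were chosen by a rule set before the data were examined: in each comparison the 10 rises and 10 falls of largest log2 fold change among genes past the threshold, with at least 1 CPM on average and groups that do not overlap, and up to 4 members of each list named, those past the threshold with the smallest adjusted p. Some genes that meet this rule, and 1 gene list past the threshold, are not reported here. Members outside the rule are said to have been chosen after their values were seen. Ratios for genes with 1 to 3 reads in a group are pooled over its libraries with exact 95% binomial intervals, which cover counting error only.

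Total depth ranged from 2480964 to 11885877 gene reads, and 3 reads correspond to 1.21 CPM in the shallowest library and 0.252 CPM in the deepest. The edgeR steps were tested on simulated counts in which 67 genes were changed 1.5-fold, 67 were changed 2-fold and 66 were changed 4-fold. For 125 µM against control they recovered 44.8% of genes changed 1.5-fold, 82.1% of those changed 2-fold and 97.0% of those changed 4-fold, with 13 unchanged genes called among 12753. For 2.5 µM against control the shares were 44.8, 85.1 and 92.4%, with 11 unchanged genes called among 12740. For 125 µM against 2.5 µM the shares were 43.3, 85.1 and 92.4%, with 23 among 12730. Changed genes recovered in that last comparison numbered 29, 57 and 61, beside the 23 unchanged ones. In every comparison, unchanged genes made up a larger share of the simulated calls than the threshold of 0.05. Baggerly's test as written here recovered at most 4.50% of genes changed 4-fold in any comparison.

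In 20 simulations with unchanged groups, all 9 libraries, controls included, were drawn independently per gene around the control means. They give the correlation that sharing 3 control libraries brings, without deviations that many genes of a real control share. Alternatives were DESeq2 1.42.0 (its size factors and its Wald test), upper-quartile scaling, no filter and a stricter filter (10 reads and 1 CPM), robust dispersion, the replicate number as a block, unique reads, glmTreat against 1.5-fold, a fit to only the 6 libraries compared, limma-voom with quantile scaling, Baggerly's test on the deposited quantile-normalised values, limma on log2(RPKM + 0.5) and log2(RPKM + 0.1), and leaving out each library in turn. Figures were drawn with matplotlib 3.10.9.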

Results

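RNA was sequenced from 9 cultures of HepG2, an established human liver tumour cell line that keeps many hepatocyte functions. The cultures were exposed for 72 h to tris(2-butoxyethyl) phosphate (TBOEP), an organophosphate ester used as a flame retardant and plasticiser, or to its solvent. There were 3 libraries at 125 µM TBOEP, 3 at 2.5 µM TBOEP and 3 controls with 0.1% DMSO alone, each from separately seeded and treated cells. Per the labels, neither concentration was cytotoxic. The reads assigned to genes numbered 10058205, 4925686 and 4023991 in control libraries 1 to 3, 10185870, 11112322 and 2480964 at 2.5 µM, and 8106587, 11885877 and 2670690 at 125 µM. Of 57773 annotated features, 12901 genes had enough reads to be tested. Intervals on counts given here cover counting error only. Coordinates are on build hg19.

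On the first principal component, which held 63.9% of the variance, the controls lay at -34.4, -16.4 and -24.1. The 125 µM libraries lay at 20.7, 27.9 and 23.1. At 2.5 µM the first and second libraries lay at -4.57 and -4.58, while the third, the shallowest of all 9, lay at 12.4. ALB, which encodes albumin, took 4.05, 2.93 and 3.50% of the gene reads of the control libraries, 3.03, 2.68 and 2.15% at 2.5 µM, and 1.39, 1.22 and 1.78% at 125 µM; it was chosen after its values were seen. Reads from introns of nuclear genes, a sign of unspliced RNA, made up 6.68% ± 0.622 of the reads in controls, 5.82% ± 1.52 at 2.5 µM and 5.05% ± 0.300 at 125 µM (mean ± SD, n = 3 libraries each).

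**Figure D1:**
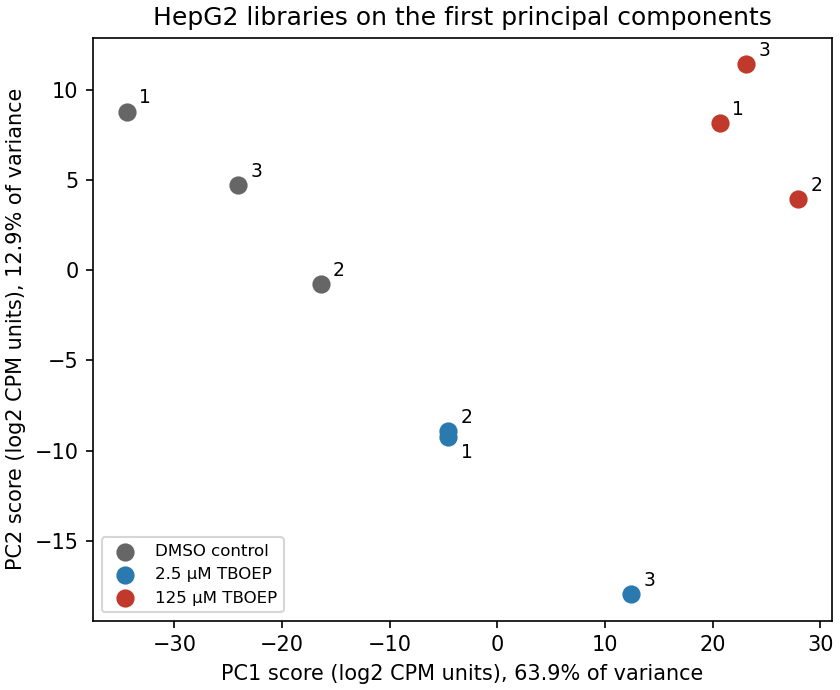
Scores of the 9 libraries on the first (63.9% of variance) and second (12.9%) principal components of log2 CPM (read counts scaled to library size), over 9211 genes. Numbers mark the replicate; control scores on the first component range from -34.4 to -16.4 and those at 125 µM from 20.7 to 27.9, with the third 2.5 µM library at 12.4.

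The first comparison asked how 72 h at the high concentration, 125 µM, changed gene expression relative to solvent. Of 74 ribosomal protein genes 61 rose and of 72 nuclear genes of respiration 53 (adjusted p = 0.525 and adjusted p = 0.395 with an estimated correlation): RPL36, a protein of the large ribosomal subunit, went from 227 ± 10.7 CPM (reads scaled to library size, mean ± SD, n = 3) in controls to 450.1 ± 35.6 at 125 µM. Of 41 targets of the amino acid and stress regulator ATF4 32 rose (adjusted p = 0.395 with an estimated correlation), with ASNS, the asparagine synthetase, at 55.4 ± 4.97 CPM in controls and 144 ± 9.23 at 125 µM (n = 3 each). Of 35 genes typical of the liver cell 15 fell and 5 rose (adjusted p = 0.434 with an estimated correlation); those that fell include the urea cycle enzyme ARG1, from 21.8 ± 7.76 to 2.03 ± 0.571 CPM, and the fibrinogen chain FGB, from 224 ± 35.5 to 68.3 ± 10.9 CPM (n = 3 each). PLIN2, which coats lipid droplets, rose from 663 ± 36.7 to 1378 ± 15.2 CPM (n = 3 each). In edgeR's quasi-likelihood test, 5180 of the 12901 genes passed an adjusted p of 0.05, 2618 higher and 2562 lower, of which 591 and 788 changed by at least 2-fold. The libraries of the groups did not overlap in 6562 genes, 50.9% of those tested, where chance gives 10%.

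Large rises, among genes with at least 1 CPM over all libraries and groups that did not overlap, included SLC16A6, of the monocarboxylate transporter family (chromosome 17, 66263167 to 66287408). It was 34.1-fold higher at 11.1 ± 4.29 against 0.353 ± 0.209 CPM (adjusted p = 3.33e-05), and overlaps ARSG. The secreted collagen-binding receptor LAIR2 (chromosome 19, 55009100 to 55021897) was 31.8-fold higher, and PLCH2, a phospholipase C (chromosome 1, 2357419 to 2436969), 16.3-fold at 13.5 ± 1.31 against 0.901 ± 0.340 CPM. KLHDC7B had 58 reads against 2, a ratio of 23.3 (counting interval 6.17 to 197). Further genes of this rank were the complement receptor C5AR1 (12.4-fold), the B cell lectin CD22 (11.9-fold), the carbonic anhydrase CA12 (11.1-fold), the water channel AQP8 (log2 fold change 3.46 ± 0.50) and the phosphodiesterase PDE2A (10.6-fold). Except for PLCH2 and SLC16A6, their means at 125 µM stayed under 10 CPM.

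Of the 10 genes of largest fall SLC6A12, a betaine and GABA transporter (chromosome 12, 299243 to 323736), had the most reads, 6326 in controls and 138 at 125 µM. It was 45.0-fold lower (adjusted p = 4.03e-05). GLP2R, an intestinal peptide hormone receptor (chromosome 17, 9725523 to 9795419), was 49.3-fold lower, at 0.868 ± 0.657 against 30.2 ± 24.3 CPM in controls. MCHR1, a receptor for melanin-concentrating hormone (chromosome 22, 41074754 to 41078818), was 32.2-fold lower, at 0.218 ± 0.131 against 5.90 ± 3.53 CPM. The water channel AQP6, which overlaps RACGAP1, was 28.1-fold lower. PLA2G2E, a secreted phospholipase, had 294 reads in controls and 1 at 125 µM, a ratio of 0.00273 (counting interval 6.9e-05 to 0.0153), and 91.9% of its reads lay in introns. GSTTP2, a pseudogene of the glutathione transferases, was 25.2-fold lower and is uncertain because it has close relatives. AC024592.9, which overlaps FUT3, and RP11-118B18.1, which overlaps FAM20A, were 56.8-fold and 37.7-fold lower and are uncertain for that reason; the call of RP11-118B18.1 was lost on RPKM (adjusted p = 0.199). RP11-290F5.2 was 24.7-fold lower, and RP11-1220K2.2 had 1 read at 125 µM against 35, a ratio of 0.0230 (counting interval 0.000565 to 0.137).

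Of the 40 gene lists fixed before the data were examined that had at least 5 tested members, 11 passed an adjusted p of 0.05 in camera with its preset correlation of 0.01, and 0 with an estimated correlation. Values for single members here and below are log2 fold changes with their SE. Of 74 genes for cytosolic ribosomal proteins, 61 rose, 0 fell and 13 did not pass (62 and 0 adjusted over the list alone). The first were RPL36 (0.99 ± 0.12), RPL12 (0.86 ± 0.12), RPL13 (0.72 ± 0.10) and RPS18 (1.14 ± 0.16), and the list had adjusted p = 2.01e-16 in camera (upward) and adjusted p = 0.525 with an estimated correlation. These genes took 3.98% ± 0.216 of all gene reads in controls and 5.99% ± 0.160 at 125 µM (n = 3 each), the groups in which intron reads were 6.68% and 5.05%. Of 72 nuclear genes for oxidative phosphorylation, 53 rose, 1 fell and 18 did not pass (56 and 1 adjusted over the list alone). They included ATP5H (0.99 ± 0.11) and ATP5G3 (0.92 ± 0.12), both subunits of ATP synthase, UQCRQ (1.41 ± 0.19) of complex III and NDUFB5 (0.90 ± 0.12) of complex I, with adjusted p = 1.24e-12 in camera (upward) and adjusted p = 0.395 with an estimated correlation.

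Of 41 targets of ATF4 and the integrated stress response, 32 rose, 2 fell and 7 did not pass (32 and 2 adjusted over the list alone). Among them DDIT4 and SESN2, both inhibitors of mTORC1 signalling, changed by 1.02 ± 0.10 and 1.18 ± 0.13, and the pseudokinase TRIB3 and ASNS by 1.39 ± 0.14 and 1.39 ± 0.14. The list had adjusted p = 5.93e-11 in camera (upward) and adjusted p = 0.395 with an estimated correlation. Of 22 genes of gluconeogenesis and the insulin axis, 10 rose, 2 fell and 10 did not pass (10 and 3 adjusted over the list alone), with PCK2 (1.05 ± 0.11), IGFBP3 (2.34 ± 0.26), PPARGC1A (0.72 ± 0.08) and IGFBP1 (2.08 ± 0.29) leading. PCK2 is the mitochondrial form of PEP carboxykinase, and IGFBP1 and IGFBP3 are secreted proteins that bind insulin-like growth factors. This list had adjusted p = 0.0156 in camera (upward) and adjusted p = 0.509 with an estimated correlation.

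Of 35 genes of hepatocyte identity and secretion, 5 rose, 15 fell and 15 did not pass (5 and 16 adjusted over the list alone). ARG1 (-3.47 ± 0.29), FGB (-1.72 ± 0.15) and the thyroxine carrier SERPINA7 (-1.03 ± 0.10) fell, while the tyrosine-degrading enzyme HPD rose (1.27 ± 0.10). The list had adjusted p = 0.00843 in camera (downward) and adjusted p = 0.434 with an estimated correlation. Of 42 genes of the acute phase, complement and coagulation, 5 rose, 18 fell and 19 did not pass (6 and 21 adjusted over the list alone), including CFI (-1.25 ± 0.10) and C8B (-2.11 ± 0.20) of complement and PROS1 (-0.84 ± 0.09) and F11 (-1.22 ± 0.15) of coagulation. This list had adjusted p = 0.000789 in camera (downward) and adjusted p = 0.395 with an estimated correlation. Of 17 Wnt and beta-catenin targets, 2 rose, 10 fell and 5 did not pass (2 and 10 adjusted over the list alone). The glutamate transporter SLC1A2 (-1.28 ± 0.10), the receptors TNFRSF19 (-0.86 ± 0.12) and LGR5 (-0.82 ± 0.13) and the transcription factor SP5 (-0.44 ± 0.08) came first, with adjusted p = 0.00977 in camera (downward) and adjusted p = 0.395 with an estimated correlation.

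Of 30 PPARA and fatty acid oxidation genes, 13 rose, 3 fell and 14 did not pass (15 and 5 adjusted over the list alone). The lipid droplet protein PLIN2 changed by 1.06 ± 0.09, the pantetheinase VNN1 by 2.86 ± 0.30, the electron transfer flavoprotein ETFB by 0.64 ± 0.09 and CPT1A, which carries fatty acids into mitochondria, by 0.99 ± 0.14. The list had adjusted p = 0.00977 in camera (upward) and adjusted p = 0.395 with an estimated correlation. Of 29 cytoskeletal, YAP and SRF target genes, 16 rose, 5 fell and 8 did not pass (16 and 5 adjusted over the list alone), with the actins ACTG1 (1.19 ± 0.10) and ACTB (1.12 ± 0.11) and the actin crosslinker FLNA (0.97 ± 0.12) higher and AJUBA (-0.94 ± 0.10) lower. It had adjusted p = 0.00306 in camera (upward) and adjusted p = 0.395 with an estimated correlation. The actins have many pseudogenes, so their values are uncertain.

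Of 48 DNA replication and G1/S genes, 15 rose, 1 fell and 32 did not pass (15 and 1 adjusted over the list alone). RRM2, a ribonucleotide reductase subunit (0.67 ± 0.11), DTL (0.76 ± 0.15) and the cell cycle factor E2F1 (0.59 ± 0.13) rose, and the helicase subunit MCM3 (-0.51 ± 0.10) fell, with adjusted p = 0.0135 in camera (upward) and adjusted p = 0.733 with an estimated correlation. Of 9 targets of the aryl hydrocarbon receptor, 4 rose, 1 fell and 4 did not pass (4 and 1 adjusted over the list alone). Those that rose included the cytochrome CYP2S1 (2.64 ± 0.22), TRIB3 and the amino acid transporter SLC7A5 (0.54 ± 0.10). CYP1A1, the most used marker of this receptor, fell (-1.65 ± 0.35), a member named after its value was seen. The list had adjusted p = 0.0132 in camera (upward) and adjusted p = 0.395 with an estimated correlation, and the mean was 0.49, whereas the median was -0.00525 and turned positive with upper-quartile or quantile scaling and on RPKM.

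Of 31 markers of endothelial, blood and immune cells in the files, 9 had enough reads to be tested. Of these ESAM (1.82 ± 0.422 against 11.2 ± 1.78 CPM), TIE1, CD68 and FCER1G rose, while VWF and the abundant lysozyme gene LYZ fell. The call of FCER1G was lost without the first control library (adjusted p = 0.0542) and that of VWF in 6 of the alternatives. Of 3 neural markers tested 2 rose, of 2 fibroblast markers 1 fell, and of 9 bile duct and progenitor markers 2 rose and 4 fell. Against a 1.5-fold minimum change, tested with glmTreat, 1085 of the 5180 genes passed, and 561 of the 5180 have most of their reads in introns. On log2(RPKM + 0.5) with limma, 2994 genes were higher and 1424 lower, a share of higher genes of 67.8% beside 50.5% for the counts.

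**Figure D2:**
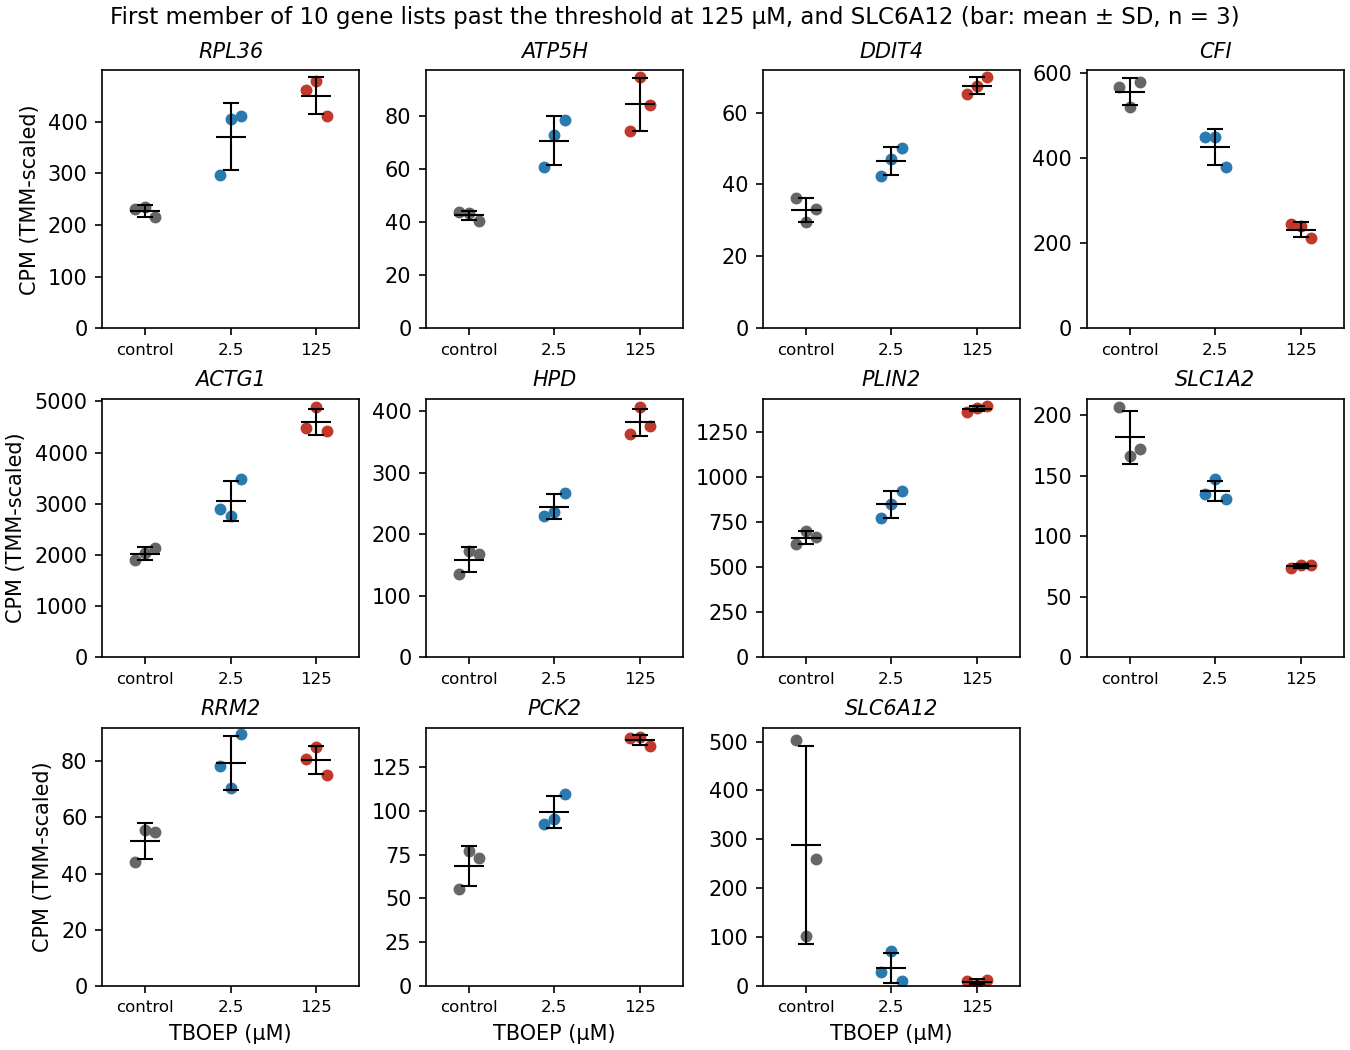
CPM (reads scaled to library size by TMM) in each library for the member with the smallest adjusted p of each of 10 gene lists past the threshold at 125 µM, and for SLC6A12. Points are libraries of the control, 2.5 µM and 125 µM groups and bars are the mean ± SD (n = 3); PLIN2 lies at 663 ± 36.7, 848 ± 74.8 and 1378 ± 15.2 CPM.

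The second comparison asked what the low concentration, 2.5 µM, did. Of 74 ribosomal protein genes 61 rose (adjusted p = 0.437 with an estimated correlation), with a list median of 0.54 against 0.59 at 125 µM: RPS18 was at 1972 ± 575 CPM against 938 ± 71.7 in controls, and at 2070.2 ± 129 at 125 µM (n = 3 each). The glucose transporters SLC2A3 and SLC2A1 rose, SLC2A3 being at 1151 ± 339 against 426 ± 89.0 CPM and SLC2A1 at 673 ± 153 against 366 ± 19.6 CPM (n = 3 each). Of 48 DNA replication genes 15 rose and 33 did not pass (adjusted p = 0.437 with an estimated correlation), with the ribonucleotide reductase subunit RRM1 at 58.2 ± 6.27 against 36.0 ± 6.15 CPM. EGR1, an immediate early transcription factor, fell from 23.8 ± 2.78 to 8.87 ± 2.24 CPM (n = 3 each). In the same edgeR fit 1425 genes passed, 776 higher and 649 lower, 123 and 121 of them by at least 2-fold, and the groups did not overlap in 28.2% of genes, where chance gives 10%.

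Among the largest rises were SLC16A6 (7.39-fold, 3.69 ± 3.45 against 0.353 ± 0.209 CPM, adjusted p = 0.034), the uncharacterised RP11-683L23.1 (7.29-fold) and PTAFR, the receptor for platelet-activating factor (chromosome 1, 28473677 to 28520447; 6.66-fold, 23.6 ± 11.1 against 3.30 ± 1.10 CPM, adjusted p = 0.00455). They were followed by the kinase DAPK2 (5.41-fold), the adhesion receptor GPR133 (4.75-fold), RP11-426C22.5 (log2 fold change 2.20 ± 0.43), the RNA-binding protein CELF5 (4.33-fold), cardiac troponin C, TNNC1 (4.15-fold), the steroid dehydrogenase HSD17B8 (4.09-fold) and RP11-473A10.2 (4.03-fold). PLAU, the urokinase gene (chromosome 10, 75668935 to 75677255), was 7.62-fold lower and SLC6A12 7.15-fold, at 36.4 ± 31.3 against 288 ± 203 CPM. SOWAHA (5.75-fold), the cadherin CDH16 (5.23-fold), the small GTPase RRAD (4.89-fold) and SPTSSB, a subunit of serine palmitoyltransferase (4.56-fold), were also lower. FUT3, a fucosyltransferase (5.31-fold), and AC024592.9 (5.82-fold) overlap each other and the pseudogene GSTTP2 (4.28-fold) has close relatives, so all of these are uncertain. NYAP1 was 5.82-fold lower on all reads, but on exon reads its adjusted p was 0.315. DAPK2, RP11-426C22.5 and RP11-473A10.2 had most of their reads in introns and too few in exons to be tested there.

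Camera called 10 lists at 2.5 µM with the preset correlation and 0 with an estimated one. Of 74 cytosolic ribosomal protein genes, 61 rose, 0 fell and 13 did not pass (67 and 0 adjusted over the list alone), led by RPS21 (1.06 ± 0.15), RPS12 (1.01 ± 0.15), RPS18 (1.07 ± 0.16) and RPL31 (0.89 ± 0.14), with adjusted p = 5.46e-43 in camera (upward) and adjusted p = 0.437 with an estimated correlation. Their share of reads was 4.84% in the first 2.5 µM library, whose intron share was 7.56%, and 6.45 and 6.44% in the others, with intron shares of 5.16 and 4.75%. Of 72 oxidative phosphorylation genes, 36 rose, 0 fell and 36 did not pass (44 and 0 adjusted over the list alone), led by ATP5G3 (0.76 ± 0.12), ATP5H (0.71 ± 0.12), COX7C (1.31 ± 0.21) and ATP5G2 (0.60 ± 0.10), with adjusted p = 1.45e-21 in camera (upward) and adjusted p = 0.437 with an estimated correlation. They took 0.664% of gene reads in the first 2.5 µM library and 0.762 and 0.770% in the others, beside 0.549 to 0.590% in the controls. Of 13 genes encoded by the mitochondrial genome, 0 rose, 3 fell and 10 did not pass (0 and 8 adjusted over the list alone), namely MT-ND6 (-0.43 ± 0.08), MT-ATP8 (-0.44 ± 0.10) and MT-ND5 (-0.38 ± 0.10), with adjusted p = 3.62e-05 in camera (downward) and adjusted p = 0.45 with an estimated correlation. MT-ATP8 overlaps MT-ATP6 and is uncertain.

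Of 48 DNA replication and G1/S genes, 15 rose, 0 fell and 33 did not pass (25 and 0 adjusted over the list alone), led by RRM1 (0.70 ± 0.12), RRM2 (0.62 ± 0.11), DTL (0.73 ± 0.15) and E2F1 (0.62 ± 0.13), with adjusted p = 1.24e-11 in camera (upward) and adjusted p = 0.437 with an estimated correlation. Of 57 G2/M and mitosis genes, 7 rose, 0 fell and 50 did not pass (11 and 0 adjusted over the list alone). They included cyclin A2 (CCNA2, 0.50 ± 0.10), the kinase CDK1 (0.68 ± 0.16), the kinetochore protein SPC24 (0.94 ± 0.23) and CDCA5 (0.61 ± 0.16), with adjusted p = 1.36e-06 in camera (upward) and adjusted p = 0.439 with an estimated correlation. Of 38 hypoxia and glycolysis genes, 17 rose, 1 fell and 20 did not pass (20 and 1 adjusted over the list alone). SLC2A3 (1.43 ± 0.19), SLC2A1 (0.87 ± 0.13) and the glycolytic enzymes TPI1 (0.45 ± 0.10) and GAPDH (0.48 ± 0.10) rose, with adjusted p = 1.08e-08 in camera (upward) and adjusted p = 0.437 with an estimated correlation. The last of these has many pseudogenes and is uncertain.

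Of 41 ATF4 targets, 12 rose, 1 fell and 28 did not pass (15 and 1 adjusted over the list alone). The serine synthesis enzyme PHGDH (0.50 ± 0.09), ASNS (0.74 ± 0.15), PCK2 (0.54 ± 0.11) and the amino acid transporter subunit SLC3A2 (0.52 ± 0.11) rose, with adjusted p = 3.54e-06 in camera (upward) and adjusted p = 0.45 with an estimated correlation. Of 22 genes of gluconeogenesis and the insulin axis, 7 rose, 1 fell and 14 did not pass (10 and 2 adjusted over the list alone). IGFBP3 (1.54 ± 0.26), FOXO1 (0.66 ± 0.12) and IGFBP1 (1.43 ± 0.28) rose and the hepatic transcription factor CREB3L3 (-1.07 ± 0.15) fell, with adjusted p = 0.0053 in camera (upward) and adjusted p = 0.437 with an estimated correlation. Of 24 heat shock genes, 0 rose, 6 fell and 18 did not pass (0 and 8 adjusted over the list alone). The chaperones HSPH1 (-0.68 ± 0.15), CHORDC1 (-0.41 ± 0.09) and HSPA4 (-0.31 ± 0.08) fell, as did HSPA1A (-0.72 ± 0.19), which is nearly identical to HSPA1B and uncertain, with adjusted p = 0.0285 in camera (downward) and adjusted p = 0.437 with an estimated correlation. Of 33 p53 targets, 0 rose, 5 fell and 28 did not pass (0 and 5 adjusted over the list alone), including TP53INP1 (-1.10 ± 0.22), PLK2 (-0.60 ± 0.15), PPM1D (-0.45 ± 0.13) and ZMAT3 (-0.28 ± 0.08), with adjusted p = 0.0433 in camera (downward) and adjusted p = 0.45 with an estimated correlation.

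The call count at 2.5 µM rested on single libraries: 213 genes passed without the first control library, 468 without the third 2.5 µM library and 707 without the third control library. With only the 6 libraries numbered 1 and 2, 0 genes passed in edgeR and 2209 had an unadjusted p under 0.05. Of 143 named or listed genes checked, 43 kept their call without the first control library. A fit to the 6 libraries of this comparison alone called 731 genes and glmTreat against 1.5-fold called 1. On log2(RPKM + 0.5) with limma, 721 genes were higher and 269 lower, a share of higher genes of 72.8% beside 54.5% for the counts.

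**Figure D3:**
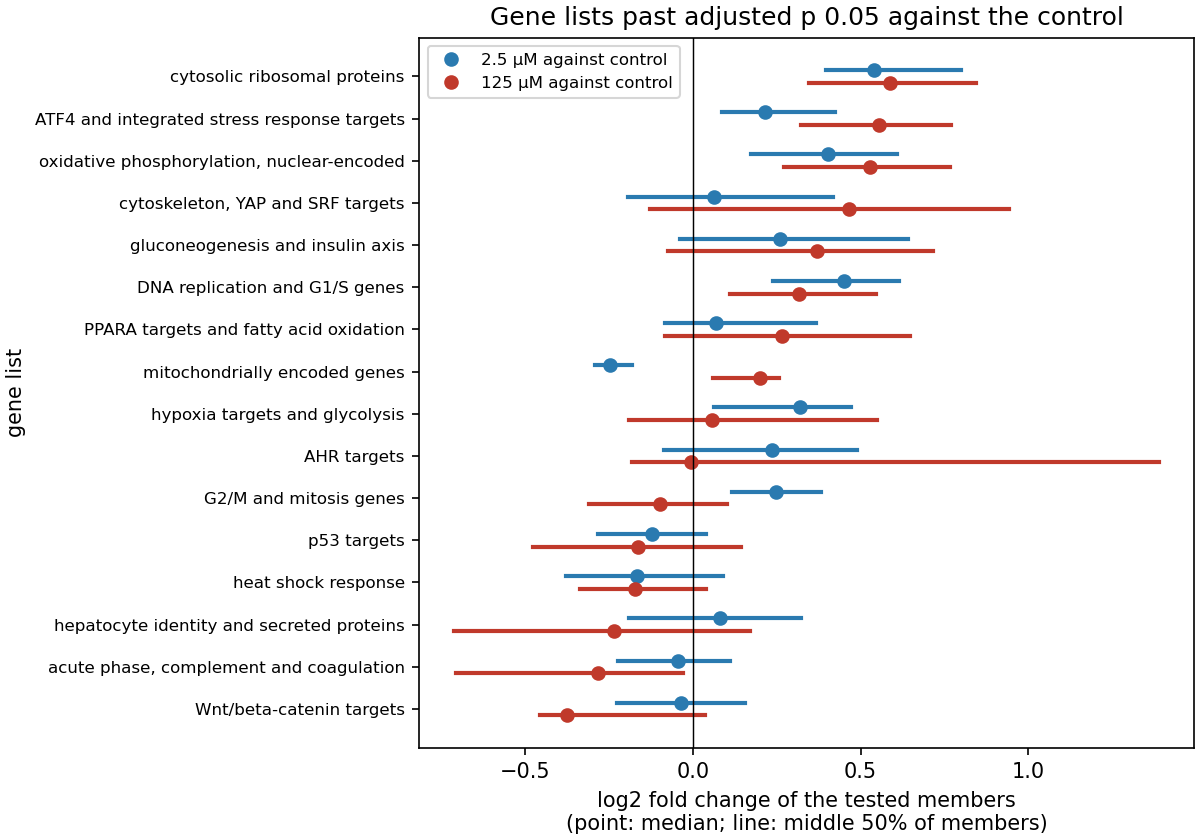
Log2 fold changes of the tested members of the 16 gene lists past an adjusted p of 0.05 in camera at 2.5 µM, 125 µM or both, against the control. Points are list medians and lines span the middle 50% of members; the ribosomal protein medians are 0.54 and 0.59, and those of the mitochondrially encoded genes -0.25 and 0.20, at 2.5 and 125 µM.

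The third comparison set 125 µM against 2.5 µM, to ask which changes differed between the concentrations. Of 57 mitosis genes 20 were lower at 125 µM and 37 did not pass (adjusted p = 0.19 with an estimated correlation), with the topoisomerase TOP2A at 226 ± 4.01 against 335 ± 28.6 CPM (n = 3 each). Against the control, the median log2 fold change of these 57 genes was 0.248 at 2.5 µM and -0.0995 at 125 µM. Of 13 genes of the mitochondrial genome 11 were higher at 125 µM than at 2.5 µM (adjusted p = 0.269 with an estimated correlation), with MT-ND2 at 2316 ± 56.0 against 1621 ± 49.2 CPM (n = 3 each). ARG1 was at 2.03 ± 0.571 against 12.9 ± 2.10 CPM and the apolipoprotein APOH at 1246 ± 69.6 against 2276 ± 227 CPM. Of 74 ribosomal protein genes 0 passed in edgeR on all reads, with 6 at an unadjusted p under 0.05, and 2 passed on exon reads. The list median was 0.000281, a sign that turned with DESeq2 size factors or upper-quartile scaling (adjusted p = 0.949 in camera). The smallest p among them was that of RPL6, with a log2 fold change of -0.21 ± 0.08 and an adjusted p of 0.0789; on exon reads RPL6 and RPSA were lower, with adjusted p of 0.0359 and 0.0443. The test called 1925 genes, 965 higher and 960 lower at 125 µM, 192 and 243 of them by at least 2-fold, and groups did not overlap in 32.8% of genes, where chance gives 10%.

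AQP8 was 9.40-fold higher at 125 µM than at 2.5 µM (4.84 ± 0.997 against 0.684 ± 0.561 CPM, adjusted p = 0.00041), PLCH2 9.17-fold and LAIR2 8.79-fold. OSCAR, an immune receptor (chromosome 19, 54597933 to 54606000), was 8.19-fold higher at 6.43 ± 0.419 against 0.873 ± 0.370 CPM, and the endothelial adhesion gene ESAM (chromosome 11, 124622026 to 124632186), which overlaps VSIG2, 6.49-fold. IGFN1 (7.34-fold), PDE2A (7.15-fold), KLHDC7B (7.13-fold) and CA12 (7.08-fold) were also higher. ACSM2A, an acyl-CoA synthetase (chromosome 16, 20462783 to 20498991), was 10.3-fold lower at 0.927 ± 0.502 against 10.5 ± 5.05 CPM, with a near-identical neighbour that makes it uncertain. TMEM27 (9.04-fold) and MCHR1 (7.53-fold) were lower. The calls of MCHR1 and PLA2G2E were lost in 5 and 7 of the alternatives. Other falls were in transcripts that overlap tested genes, RP11-118B18.1 (log2 fold change -3.70 ± 0.72), RP11-511B23.1 (9.43-fold) and AP000320.7 (8.51-fold), and are uncertain. CTA-85E5.10, which overlaps MTMR3, and PXDNL have all their reads in introns and are uncertain. PLA2G2E, RP11-1220K2.2, PXDNL and CTA-85E5.10 had 1, 1, 2 and 3 reads at 125 µM, and their pooled ratios were 0.0158 (counting interval 0.000395 to 0.0914), 0.0429 (0.00104 to 0.263), 0.0686 (0.00795 to 0.270) and 0.0965 (0.0189 to 0.308).

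Camera called 15 lists between the concentrations with the preset correlation and 0 with an estimated one. Of 57 G2/M and mitosis genes, 0 rose, 20 fell and 37 did not pass (0 and 37 adjusted over the list alone), led by TOP2A (-0.58 ± 0.08), KIF20A (-0.80 ± 0.13), NUSAP1 (-0.65 ± 0.12) and CKAP2 (-0.51 ± 0.10), with adjusted p = 7.87e-13 in camera (downward) and adjusted p = 0.19 with an estimated correlation. Of 13 mitochondrially encoded genes, 11 rose, 0 fell and 2 did not pass (13 and 0 adjusted over the list alone), led by MT-ATP8 (0.65 ± 0.10), MT-ND2 (0.51 ± 0.08), MT-ND4 (0.59 ± 0.10) and MT-ND1 (0.50 ± 0.10), with adjusted p = 2.36e-09 in camera (upward) and adjusted p = 0.269 with an estimated correlation. MT-ATP8 and MT-ND4 overlap MT-ATP6 and MT-ND4L and are uncertain. All reads from the mitochondrial genome made up 9.70, 9.51 and 8.85% of gene reads at 125 µM, 7.18, 7.19 and 6.82% at 2.5 µM, and 7.64, 7.58 and 8.64% in controls. Of 35 hepatocyte genes, 2 rose, 16 fell and 17 did not pass (2 and 18 adjusted over the list alone), led by SERPINA7 (-1.06 ± 0.10), APOH (-0.87 ± 0.09), ARG1 (-2.73 ± 0.30) and FGB (-1.30 ± 0.15), with adjusted p = 6.03e-09 in camera (downward) and adjusted p = 0.19 with an estimated correlation. Of 42 acute phase, complement and coagulation genes, 0 rose, 15 fell and 27 did not pass (1 and 17 adjusted over the list alone), led by CFI (-0.88 ± 0.09), C8B (-1.75 ± 0.20), PROS1 (-0.59 ± 0.09) and C8A (-1.06 ± 0.16), with adjusted p = 3.47e-06 in camera (downward) and adjusted p = 0.19 with an estimated correlation.

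Of 41 ATF4 targets, 14 rose, 2 fell and 25 did not pass (24 and 2 adjusted over the list alone). SESN2 (0.99 ± 0.12), TRIB3 (0.90 ± 0.14) and the tryptophan tRNA synthetase WARS (0.81 ± 0.13) were higher and the amino acid transporter SLC38A2 (-0.60 ± 0.10) lower, with adjusted p = 1.28e-07 in camera (upward) and adjusted p = 0.378 with an estimated correlation. Of 29 cytoskeletal, YAP and SRF targets, 16 rose, 2 fell and 11 did not pass (17 and 2 adjusted over the list alone), among them EGR1 (1.44 ± 0.16), AJUBA (-0.87 ± 0.10), FOSL1 (1.04 ± 0.14) and ACTB (0.63 ± 0.11), with adjusted p = 6.79e-05 in camera (upward) and adjusted p = 0.196 with an estimated correlation. Of 17 Wnt targets, 1 rose, 8 fell and 8 did not pass (1 and 8 adjusted over the list alone), among them DKK1 (-0.999 ± 0.11), SLC1A2 (-0.87 ± 0.10), TNFRSF19 (-0.88 ± 0.12) and TCF7 (0.85 ± 0.13), with adjusted p = 0.000228 in camera (downward) and adjusted p = 0.183 with an estimated correlation. Of 30 PPARA and fatty acid oxidation genes, 8 rose, 0 fell and 22 did not pass (9 and 1 adjusted over the list alone), led by PLIN2 (0.70 ± 0.09), VNN1 (1.81 ± 0.26), CPT1A (0.75 ± 0.14) and ACADVL (0.43 ± 0.08), with adjusted p = 0.00232 in camera (upward) and adjusted p = 0.19 with an estimated correlation. Of 9 aryl hydrocarbon receptor targets, 3 rose, 0 fell and 6 did not pass (3 and 1 adjusted over the list alone), including CYP2S1 (1.82 ± 0.20) and TRIB3 (0.90 ± 0.14), with adjusted p = 0.0279 in camera (upward) and adjusted p = 0.278 with an estimated correlation. The mean of that list was 0.34 and its median -0.000888, which was positive on RPKM.

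Of 25 steroid hormone metabolism genes, 0 rose, 9 fell and 16 did not pass (1 and 9 adjusted over the list alone). The oestrogen sulfotransferase SULT1E1 (-2.20 ± 0.37), the ketosteroid reductases AKR1C2 (-1.18 ± 0.22) and AKR1C3 (-0.54 ± 0.11), which are close copies and uncertain, and HSD17B7 (-0.72 ± 0.16) were lower, with adjusted p = 0.0109 in camera (downward) and adjusted p = 0.221 with an estimated correlation. Of 38 hypoxia and glycolysis genes, 5 rose, 16 fell and 17 did not pass (6 and 18 adjusted over the list alone). CA12 (2.82 ± 0.42), the phosphofructokinase PFKP (0.90 ± 0.14) and DDIT4 (0.55 ± 0.10) were higher and PDK1 (-0.48 ± 0.09) lower, with adjusted p = 0.0123 in camera (downward) and adjusted p = 0.643 with an estimated correlation. Against the control, the median log2 fold change of this list was 0.319 at 2.5 µM and 0.0571 at 125 µM.

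Of 11 thyroid hormone-responsive genes, 1 rose, 4 fell and 6 did not pass (2 and 6 adjusted over the list alone). SERPINA7 (-1.06 ± 0.10), KLF9 (-0.64 ± 0.13) and the receptor THRB (-0.43 ± 0.11) were lower and CPT1A (0.75 ± 0.14) higher, with adjusted p = 0.018 in camera (downward) and adjusted p = 0.269 with an estimated correlation. Of 31 extracellular matrix and adhesion genes, 9 rose, 5 fell and 17 did not pass (11 and 7 adjusted over the list alone), including ITGA2 (1.07 ± 0.11), TIMP1 (1.23 ± 0.17) and TIMP2 (0.85 ± 0.14), with adjusted p = 0.0347 in camera (upward) and adjusted p = 0.278 with an estimated correlation. Of 28 phase II enzymes of xenobiotic metabolism, 1 rose, 7 fell and 20 did not pass (3 and 8 adjusted over the list alone). The glutathione transferase GSTA1 (-1.58 ± 0.21) and the glucuronosyltransferase UGT2B10 (-0.87 ± 0.12), both with near-identical relatives and uncertain, HNMT (-0.56 ± 0.08) and SULT1E1 were lower, with adjusted p = 0.0472 in camera (downward) and adjusted p = 0.29 with an estimated correlation.

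Without the second 125 µM library 799 genes passed between the concentrations, without the first 1043, without the third 1252, and without the second 2.5 µM library 1015. Against a 1.5-fold minimum change 122 passed, and on log2(RPKM + 0.5) 782 genes were higher and 366 lower, a share of higher genes of 68.1% beside 50.1% for the counts.

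The fold changes at both concentrations were then set side by side. Of the 1425 genes called at 2.5 µM, 1241 (87.1%) were also called at 125 µM in the same direction, 659 higher and 582 lower, such as ASNS (0.74 ± 0.15 at 2.5 µM and 1.39 ± 0.14 at 125 µM) and SLC6A12 (-2.84 ± 0.54 and -5.49 ± 0.68). Lists of these sizes that were independent would share 157 and 129 genes. In 20 simulations with unchanged groups, all 9 libraries, controls included, were redrawn, and a mean of 0.05 and at most 1 call was shared. They called at most 2 genes at 125 µM and 5 at 2.5 µM, so nearly no shared calls could arise. That number does not measure the overlap that shared controls bring. Of the 1241 shared genes, 974 changed more at 125 µM. A difference between the concentrations was itself called for 287 of them, 285 of these with the larger change at 125 µM. Over the 1241 shared genes, the median ratio of the log2 change at 2.5 µM to that at 125 µM was 0.747. That ratio leaves out the 3935 genes called at 125 µM only. Requiring a call at 2.5 µM favours genes with larger changes there. Across all tested genes, which are not independent replicates, Pearson's correlation of the log2 fold changes was 0.78, against a mean of 0.529 in the simulations (0.512 to 0.547). The covariance was 0.232 against 0.0269 simulated, a difference of 0.205, and 78.2% of genes had the same sign against 67.4%. The 3 controls could not be divided into sets of at least 2 libraries each, so part of the excess may come from the shared controls. The shared calls numbered 189 without the first control library, 438 without the third 2.5 µM library and 638 without the third control library. With only the 6 libraries numbered 1 and 2, 0 genes were called at 2.5 µM, so 0 were shared. Only 4 genes were called in opposite directions.

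**Figure D4:**
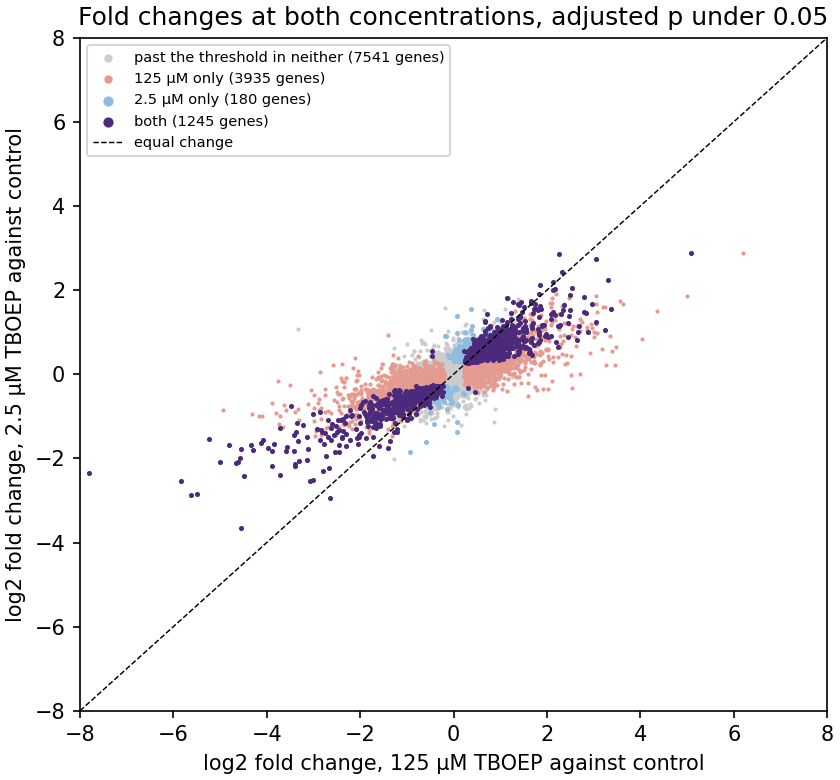
Log2 fold change of each of the 12901 tested genes at 125 µM (x axis) and at 2.5 µM (y axis), both against the control. Colours mark genes past an adjusted p of 0.05 at both concentrations (1241 genes in the same direction and 4 in opposite directions), at 125 µM only (3935), at 2.5 µM only (180) or at neither, and the dashed line marks equal change.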

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

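The tests of the endothelial and blood cell genes, the test of the intron read share for ribosomal protein genes and the test for RNA of 125 µM cultures in a 2.5 µM library were chosen after their results had been seen, and their bounds were set with those results known. Only 4 genes passed at both concentrations in opposite directions, and for each of them the difference between 125 µM and 2.5 µM passed too. That difference is the first change minus the second in the same fit, so its passing adds no separate support. DKK1, a secreted Wnt inhibitor, changed by -0.45 at 125 µM and 0.55 at 2.5 µM on the log2 scale, a difference of -0.999. RAB11FIP4 changed by -0.46 and 0.43, a difference of -0.89. ANTXR2, an anthrax toxin receptor, changed by 0.47 and -0.42, a difference of 0.89. TRIB1, a pseudokinase of hepatic lipid metabolism, changed by 0.32 and -0.32, a difference of 0.64. The calls at 2.5 µM for ANTXR2, TRIB1 and RAB11FIP4 were lost in 11, 8 and 5 of the alternatives run on single genes, and that of DKK1 in 0.

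Some endothelial and blood cell genes rose at 125 µM although the cultures are a single hepatic line: of 9 markers with enough reads to be tested, ESAM (32 to 274 reads), TIE1 (8 to 56), CD68 (31 to 134) and FCER1G (29 to 93) rose and 2 fell, while of 3 neural markers tested 2 rose, of 2 fibroblast markers 1 fell, and of 9 bile duct and progenitor markers 2 rose and 4 fell. Cells of another type cannot be told apart from a change in the HepG2 cells: over all members, the counting interval of the ratio of 125 µM to control lay above 1 for 3 of 11 endothelial markers (a share of 0.273) and 4 of 20 blood and immune markers (a share of 0.2), and below 1 for 2 of each list, 22 of the 31 having too few reads to be tested. KDR, TEK, ERG, EMCN and PTPRC had 0 reads at 125 µM and VWF fell (41 to 11 reads), which speaks against such cells. However, KDR and PTPRC had 0 reads in every group, so whether the counting can detect them is not known. By contrast, CDH5 (4 to 31 reads, ratio 6.23, interval 2.20 to 24.3) moved with ESAM (6.88) and TIE1 (5.63). Intron reads are argued against, since the exon-read log2 fold changes of the 4 genes that rose were 0.993 of those of all reads in the median (0.978 to 1.31), and calls were lost for FCER1G without the first control library (adjusted p = 0.0542) and for VWF in 6 of the alternatives (up to 0.385). A change of these genes in the HepG2 cells themselves under TBOEP stays open and was not tested, as do exon reads of overlapping genes for ESAM (VSIG2), CD68 and FCER1G.

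Ribosomal protein genes had a median log2 fold change of 0.54 at 2.5 µM and 0.59 at 125 µM, with 61 and 61 of 74 called higher, and oxidative phosphorylation genes of 0.40 and 0.53, with 36 and 53 of 72. Gene length is argued against: over the 131 of 146 members with a transcript length (medians of 0.50 and 0.54), 406 other genes matched on length and, more loosely, on expression (median log2 CPM of 6.22 against 7.66) moved by 0.02 and 0.04, at most 0.0681 of the rise of the members. Over the 10702 genes with a length, list members included, shorter genes had slightly higher fold changes. Spearman's correlation of length and log2 fold change was -0.159 at 2.5 µM and -0.137 at 125 µM. Without the 10 most read genes, and with DESeq2 size factors, the rise kept at least 0.989 of its size, and leaving out single libraries kept at least 0.831 of it (medians of 0.55 to 0.58 at 125 µM and 0.42 to 0.62 at 2.5 µM). The share of intron reads cannot be told apart from the groups: its trend within groups gives at most 0.282 of the rise (upper 95% bound 0.564; a share of 0.487 without the third control library), and the slope of -0.09 turns to 0.07 per percentage point without the first 2.5 µM library, so it may account for none or part of the rise. A treatment effect stays open, as do GC content and differences between cultures, which were not tested.

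The third 2.5 µM library lay 0.596 of the way from its group to the 125 µM libraries on the first principal component. Depth and the share of intron reads are argued against, because the gap kept 0.894 of its size with all libraries thinned to 2480964 reads and 0.976 on exon reads. RNA of a 125 µM culture in this library cannot be told apart from the other explanations: the 6 genes at least 8-fold higher at 125 µM than in the other 2.5 µM libraries have a median of 3 reads each here. Their median level as a share of that at 125 µM was 0.290 of the share implied by the position of 0.596, and together 22 reads were seen (exact Poisson interval 13.8 to 33.3) where 58.2 were implied. All 6 were higher here than in both other 2.5 µM libraries. They were chosen for low levels in those other libraries, which favours this result in advance, so it decides nothing. On the second component the library lay at -18.0, the others of its group at -9.27 and -8.91 and those at 125 µM at 3.93 to 11.4. Its mitochondrial reads were 6.82%, beside 7.18 and 7.19% in its group and 8.85 to 9.70% at 125 µM. Both values lie away from 125 µM. A difference between cultures at 2.5 µM, in dose received or growth, stays open and was not tested.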

How the results depend on the processing

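The alternatives added after the data were seen were exon reads only, only the 6 libraries numbered 1 and 2, and all libraries thinned to 2480964 reads. Of the named and listed genes recomputed, 0 changed direction; over all called genes, 2 were called the other way on RPKM and 1 on exon reads, at 125 µM. Against 1.5-fold, glmTreat called 1085, 1 and 122 genes (125 µM against control, 2.5 µM against control, 125 against 2.5 µM). Baggerly's test called 0, 1 and 0, with 3711, 1421 and 1985 at an unadjusted p under 0.05; it recovered few simulated changes. Thinning, which leaves fewer reads and 11083 genes, left 1958, 333 and 426 genes, 285 shared calls and a correlation of 0.68. With only libraries 1 and 2, edgeR called 0 genes at 2.5 µM (2209 at an unadjusted p under 0.05), 923 between the concentrations and 0 shared. The fit to only the 6 libraries compared called 731 at 2.5 µM. Between the concentrations, limma called 1148 genes on log2(RPKM + 0.5) and 1104 on log2(RPKM + 0.1). Without the filter the correlation was 0.61.

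Leaving out each library gave 213 to 2050 genes at 2.5 µM, 799 to 2230 between the concentrations, 189 to 1786 shared calls and a correlation of 0.70 to 0.82, and 3557 to 5351 genes at 125 µM. The lowest at 2.5 µM and of the shared calls came without the first control library, and the cause was not tested. Camera with an estimated correlation called 0 lists in each comparison, where 11, 10 and 15 passed with the preset one, and fry called 21 at 125 µM. The other alternatives kept every count made with them within 1.5-fold, DESeq2's Wald test with 4196, 1236 and 1373 genes and exon reads with 4795, 1631 and 1885 among them. For upper-quartile scaling, the stricter filter, robust dispersion, unique reads, the Wald test and limma-voom, only gene calls were counted, not shared calls or lists.

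With the replicate block (the replicate number as a covariate) the counts were 5066, 1274 and 1771 genes and 1120 shared calls, and no list count moved by more than 1. The numbers gave no consistent pairing of the libraries: correlations of deviations between same-numbered libraries ran from -0.35 to 0.31, 3 of 9 over 0.1. In both other groups at once, 3 of 9 libraries correlated best with their own number, and how often chance gives this was not tested. Depth limits low genes most: in the shallowest library 3 reads equal 1.21 CPM, and most of the genes with the largest ratios lie under 10 CPM.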

Other observations

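The tests of other splits in the last paragraph were set before their results were seen. Several lists did not pass at 125 µM as lists while single members changed by much. Of 10 metal-response genes 5 rose and 1 fell (adjusted p = 0.21 for the list in camera): the metallothioneins MT2A (2.23 ± 0.19), MT1E (1.82 ± 0.21) and MT1X (0.84 ± 0.25), members of a near-identical family and uncertain, were higher and the zinc importer SLC39A14 (-1.29 ± 0.18) lower, values being log2 fold changes with their SE. MT1X lost its call without the second 125 µM library or the third control library (adjusted p up to 0.125). Of 28 lipid droplet and lipoprotein genes 10 rose and 9 fell (adjusted p = 0.714): PLIN2, the lipid droplet protein CIDEC (3.02 ± 0.31) and APOA2 (1.03 ± 0.11) were higher and LCAT, which esterifies cholesterol in lipoproteins (-1.35 ± 0.13), lower. Of 18 bile acid and FXR genes 5 rose and 6 fell (adjusted p = 0.584): the bile acid exporter subunit SLC51A (3.04 ± 0.30) was higher, and the bile acid receptor NR1H4 (-1.59 ± 0.20), the FGF19 co-receptor KLB (-2.21 ± 0.24) and the phospholipid exporter ABCB4 (-0.90 ± 0.12) were lower.

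Of 32 nuclear receptors 6 rose and 14 fell at 125 µM (adjusted p = 0.0844), with the xenobiotic receptor NR1I2 higher (1.41 ± 0.17) and THRB (-0.86 ± 0.11) and NR2F1 (-0.83 ± 0.11) lower. Of 15 targets of PXR and CAR 4 rose and 6 fell (adjusted p = 0.918), with TSKU (1.37 ± 0.11), FKBP5 (0.66 ± 0.11) and ABCC3 (0.79 ± 0.13) higher and CYP3A43 (-4.12 ± 0.55), of a family of close copies and uncertain, lower; its call was lost on RPKM (adjusted p = 0.346). Of 14 oestrogen-responsive genes 6 rose and 3 fell (adjusted p = 0.245): TFF1 (2.84 ± 0.29), CA12 and IGFBP4 (1.28 ± 0.20) were higher and GREB1 (-0.56 ± 0.11) lower. Of 31 NRF2 targets 11 rose and 8 fell (adjusted p = 0.584), with the biliverdin reductase BLVRB (1.40 ± 0.16) and the cystine transporter SLC7A11 (1.17 ± 0.16) higher and GPX2 (-1.51 ± 0.17) and AKR1C2 (-1.65 ± 0.23) lower. Of 15 NF-kB targets 3 rose and 5 fell (adjusted p = 0.584): the inhibitor NFKBIA (-1.82 ± 0.23), NFKB1 (-0.61 ± 0.10) and BCL3 (-1.35 ± 0.23) were lower and IL32 (0.74 ± 0.10) higher.

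Each comparison of 3 libraries with 3 has 10 splits, too few for a share under 0.05. Every other split mixes the groups compared, so a real difference widens the spread within its groups. Few gene calls there are therefore not the level that unchanged groups would give. At 125 µM the real split called 5180 genes and the highest of the other 9 called 0, so 1 of the 10 splits had as many. At 2.5 µM the real split called 1425 and the highest other 1, again 1 of 10, and between the concentrations 1925 and 0, also 1 of 10. For gene lists tested by camera with the preset correlation, at 125 µM 2 of the 10 splits called as many as the real 11 (highest other 11), at 2.5 µM 2 of 10 called as many as the real 10 (highest other 12), and between the concentrations 1 of 10 called as many as the real 15 (highest other 14).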
